A study of Rattus norvegicus with 9 samples.

How the data were processed

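Values were deposited for 9 RNA-seq libraries of rat primary aortic vascular smooth muscle cells: 3 Control (DMSO), 3 PDGF-BB and 3 PDGF-BB+PTUPB. Per the labels, cells of passages 4 to 8 were grown in 20% serum, kept 12 h without serum and treated in 2% serum. PTUPB (0.5 µM) was given 2 h before PDGF-BB, and PDGF-BB was given for 24 h, at 10 ng/mL per the sample labels and 20 ng/mL per the series design. Per the labels, poly(A) RNA was taken from TRIzol extracts, primed at random and sequenced paired-end. Groups were taken from the sample labels.

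Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1, aligned with HISAT2 2.0.1 and counted with HTSeq 0.6.1. The file deposited by the authors holds an expected count for each of 32623 genes in each library, and 978 genes have a value that is not whole, which HTSeq alone does not give, so how these counts were made is not known. The same deposited file gives FPKM, and FPKM recomputed from the deposited counts and exonic lengths lay within 0.006 of the deposited value for 100% of values. The notes name the build mm10, a mouse build, whereas all 32623 identifiers are rat Ensembl identifiers. No coordinates are therefore given, and GC content was not analysed here because no genome was at hand. The strand used for counting is not stated.

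Counts summed to 12729187 to 16911050 per library, and 3 counts correspond to 0.177 to 0.236 CPM. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested (11197). The test planned before the data were examined was limma on log2(FPKM + 1), with edgeR as an alternative in case counts were deposited. Because the file also holds counts, edgeR became the main test after the file was opened and limma the alternative. Counts were rounded to whole numbers and fitted with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test, group as the only term, all 9 libraries in 1 fit, 6 residual degrees of freedom) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, two-sided, in 3 comparisons: PDGF-BB against Control, PDGF-BB+PTUPB against PDGF-BB and PDGF-BB+PTUPB against Control. CPM are TMM-scaled. The biological coefficient of variation was 0.137.

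Gene lists were fixed before the data were examined: contractile and synthetic smooth muscle, S phase, G2/M phase, cyclins and CDK inhibitors of G1, prostanoid and leukotriene pathway, cytochrome P450 and epoxide hydrolase pathway, extracellular matrix, NF-kB and cytokine response, interferon response, immediate early and MAPK feedback, cholesterol synthesis, fatty acid synthesis, PPAR targets and fatty acid oxidation, glycolysis and hypoxia, amino acid and ATF4 response, endoplasmic reticulum chaperones, NRF2 targets, p53 targets, TGF-beta and BMP targets, PDGF ligands and receptors, heat shock, ribosome biogenesis, mitochondrially encoded genes, and markers of endothelial, adventitial fibroblast, macrophage, chondrogenic and osteogenic, pericyte and Schwann cells. Of these 30 lists, 26 had at least 5 tested genes and were tested with camera in limma 3.58.1 at the preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The fry test of limma was planned beside camera and also run. It asks whether the genes of a list changed, not whether they changed more than other genes. Members were also adjusted over the list alone. Symbols that had no value in the file (E2f1, Ccnb2, Cdkn2d, Ptgis, Ptgdr, Cyp2j3, Col1a2, Col6a3, Cd36, Gapdh, Srxn1, Pgd, Bbc3, Tnfrsf10b, Hspa1a, Heatr1 and Pecam1) were not analysed here.

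Genes were named by a rule set before the data were examined: in each comparison the 8 largest rises and 8 largest falls among called genes with a mean FPKM of at least 2 in the higher group, groups that did not overlap and a named symbol, up to 4 called members of a list by smallest p (or the 2 most abundant if none was called), and always Ptgs2, Ephx2, Pdgfrb, Acta2, Myh11, Tagln, Cnn1, Spp1, Klf4, Ccnd1 and Mki67. Genes named outside the rule are said to be so where they appear, and some genes that the rule would name are not reported here.

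The share of the PDGF-BB change left with PTUPB was a ratio of second moments about 0, not about the means. Its numerator was the mean product of the PDGF-BB and PDGF-BB+PTUPB contrasts against Control, less the sampling covariance from the shared Control libraries. Its denominator was the mean square of the PDGF-BB contrast, less its sampling variance. For a list whose genes moved together, the share therefore mostly reflects the mean change of the list. To see what shared PDGF-BB libraries do alone, 20 sets of groups without any effect were simulated with the dispersions of the data. Genes were drawn independently of one another, so deviations that many genes of a library share were not simulated. The linear weight of a gene was its position between the mean of Control (0) and the mean of PDGF-BB (1) on the CPM scale.

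On simulated data with 11197 genes, edgeR recovered 34 of 67 genes set to a 1.5-fold change (50.8%), 55 of 67 at 2-fold (82.1%) and 63 of 66 at 4-fold (95.5%) in the PDGF-BB comparison, with 13 false calls (7.14% of its calls). In PDGF-BB+PTUPB against PDGF-BB it recovered 9 of 67 at 1.414-fold and 48 of 66 at 2-fold with 2 false calls (3.33%), and in PDGF-BB+PTUPB against Control 5 of 67 and 43 of 66 with 4 false calls (7.41%). Of 200 random lists of 30 genes, camera gave an unadjusted p under 0.05 for 0, 1 and 2 in the 3 comparisons. These lists held only genes without a set change, simulated independently of one another. They do not show how often camera errs for lists of correlated genes. A share of 0.5 set for changed genes was returned as 0.444 over all genes and 0.485 over the 200 changed genes.

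Alternatives set before the data were examined were limma on log2(FPKM + 1) with trend, without trend and with robust estimation, pseudocounts of 0.5 and 0.1, TPM and quantile scaling, no filter and a filter of FPKM 5, median-of-ratios scaling, only the 6 libraries compared, the replicate number as a block, DESeq2 1.42.0, an estimated camera correlation and leaving out each library in turn. Added after seeing the data were library totals as the only scaling, a gene length offset and counts thinned to the smallest total. Covariances about the means for the share left, and leaving out Control replicate 2 and PDGF-BB replicate 3 together, were also added then. Both libraries lay furthest from the rest of their groups, so leaving them out by itself lowers the spread and favours more calls. A search of 869 Gene Ontology biological process terms of 15 to 200 tested genes by camera was also chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.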

Results

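RNA-seq profiles were obtained from 9 libraries of rat primary aortic vascular smooth muscle cells (VSMC), the contractile cells of the artery wall, with 3 libraries in each of 3 groups. Control cells received DMSO. The PDGF-BB group received platelet-derived growth factor BB, a mitogen for smooth muscle cells, and the PDGF-BB+PTUPB group was pretreated with PTUPB before the same growth factor. PTUPB is a small molecule that inhibits both cyclooxygenase-2 (COX-2, gene Ptgs2) and soluble epoxide hydrolase (sEH, gene Ephx2), enzymes of arachidonic acid metabolism. Counts over all genes summed to 13897169, 16911050 and 15453654 in Control replicates 1 to 3 and to 12729187, 12959291 and 13002257 in PDGF-BB replicates 1 to 3. They summed to 13832505, 16738133 and 13528312 in PDGF-BB+PTUPB replicates 1 to 3. A total of 11197 genes were tested. Levels are given as CPM (counts scaled to library size, mean ± SD, n = 3 libraries per group) and changes as log2 fold changes ± SE. The comparisons, gene lists, thresholds and the rule for naming genes were set before the data were examined. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

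The groups separated along the leading principal component, which held 50.9% of the variance: Control libraries lay between -30.6 and -28.2, PDGF-BB+PTUPB libraries between -10.7 and -1.66, and PDGF-BB libraries between 31.0 and 42.0. The next component (13.6%) set Control replicate 2 (-21.5) and PDGF-BB replicate 3 (-25.9) apart from the other 7 libraries, which lay between 0.660 and 18.8. In these libraries longer genes read lower than in the rest of their group, with Spearman correlations, across genes, between deviation and exonic length of -0.389 and -0.381. Trends of similar size in the other direction were seen in Control replicate 1 (0.348) and PDGF-BB replicate 2 (0.350). Deviations were taken from the other 2 libraries of a group, so a trend in 1 library by itself brings opposite trends in the others. Genes are not independent replicates, so these correlations are descriptions. Mitochondrially encoded transcripts took 2.81% to 3.66% of the counts and the 10 most abundant genes 7.79% to 8.77%.

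The comparison of PDGF-BB with Control describes the growth factor response on which PTUPB was tested. Many of the largest rises were in genes of mitosis. Cdc20 (ENSRNOG00000028415), an activator of the anaphase-promoting complex, rose from 7.16 ± 1.38 to 82.9 ± 2.000 CPM, a log2 change of 3.54 ± 0.17 (edgeR adjusted p = 2.72e-06). All 29 tested members of the G2/M list rose (29 adjusted over the list alone), with a median log2 change of 2.89. Of the S phase genes, 24 of 29 rose and 0 fell (25 adjusted over the list alone), with a median of 1.23. Among them, the mitotic kinesin Kif20a changed by 3.79 ± 0.30, the survivin gene Birc5 by 3.51 ± 0.20, the mitotic kinase gene Aurka by 3.01 ± 0.16, and the thymidylate synthase gene Tyms by 1.94 ± 0.13 on the log2 scale. Pttg1 (securin, 3.79 ± 0.25), Cenpw (a centromere protein, 3.66 ± 0.19), Knstrn (a kinetochore and spindle protein, 3.56 ± 0.16) and Oip5 (3.79 ± 0.35) were also among the 8 largest rises by the naming rule, as was Anos1, a low gene with 0 counts in Control, 18 in PDGF-BB and 0 in PDGF-BB+PTUPB. Against a floor of 3 counts over a group, Anos1 was at least 6.84-fold higher in PDGF-BB than in Control and at least 6.63-fold higher than in PDGF-BB+PTUPB; such floors cover counting error only. Of the G1 cyclins and cyclin-dependent kinase (CDK) inhibitors, 7 of 15 rose and 2 fell (8 and 2 adjusted over the list alone). Cyclin D1 (Ccnd1) went from 144 ± 21.9 to 248 ± 46.4 CPM, the CDK inhibitors Cdkn1a (0.75 ± 0.09) and Cdkn2a (1.64 ± 0.22) rose with it, and the growth arrest gene Gas1 fell (-1.82 ± 0.22). The camera test gave adjusted p = 3.48e-59 for the G2/M list, 8.58e-20 for the S phase list and 0.0759 for the G1 list. With an estimated correlation the G2/M and S phase lists both had an adjusted p of 0.113, and the G1 list 0.197. The G1 list reached 0.0466 without Control replicate 3. Over all 26 alternatives the G1 list ranged from 0.0310 to 0.197.

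Genes of lipid synthesis and of the interferon response rose as well. The sterol methyl oxidase gene Msmo1 rose from 138 ± 26.3 to 281 ± 25.7 CPM (1.03 ± 0.15, edgeR adjusted p = 5.59e-04), and 15 of 23 cholesterol synthesis genes rose with 0 falling (18 adjusted over the list alone). They also included Fdft1 (0.81 ± 0.10) and Fdps (0.88 ± 0.13). In the fatty acid synthesis list 9 of 14 genes rose and 1 fell (9 and 1 adjusted over the list alone); Acsl3 and Fads2 changed by 0.74 ± 0.11 and 0.67 ± 0.12, while the falling gene, Gpam (-1.32 ± 0.13), encodes an acyltransferase of glycerolipid synthesis. Of 23 interferon response genes 16 rose and 0 fell (16 adjusted over the list alone). The transcription factor gene Irf7 changed by 1.67 ± 0.15 and Mx2, a GTPase gene, went from 1.54 ± 0.859 to 13.4 ± 1.25 CPM (3.10 ± 0.38). Among p53 targets 5 of 18 rose and 0 fell (5 adjusted over the list alone), including the p53 inhibitor gene Mdm2 (0.80 ± 0.09), Phlda3 (0.69 ± 0.09) and Ccng1 (0.65 ± 0.13). Camera gave adjusted p = 6.85e-06 for cholesterol synthesis, 0.0210 for fatty acid synthesis, 7.92e-07 for the interferon response and 0.0180 for p53 targets. With an estimated correlation none of the calls held, at adjusted p = 0.353 for both lipid lists and 0.113 for the interferon and p53 lists. Without Control replicate 2 and PDGF-BB replicate 3 together, the fatty acid list had a camera adjusted p of 0.0824, within a range of 0.00398 to 0.353 over the 26 alternatives.

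Several signalling groups and the adventitial fibroblast markers fell. Pdgfrb (ENSRNOG00000018461), the receptor that binds PDGF-BB, dropped from 1173 ± 23.9 to 570.2 ± 24.9 CPM, a log2 change of -1.04 ± 0.07 (edgeR adjusted p = 1.02e-05). In the list of PDGF and related ligands and receptors 9 of 14 genes fell and 1 rose (9 and 1 adjusted over the list alone), with Pdgfra at -0.97 ± 0.13, Vegfa at -0.58 ± 0.07 and the rising ligand gene Pdgfc at 0.88 ± 0.10. Of 20 TGF-beta and BMP targets 11 fell and 2 rose (12 and 2 adjusted over the list alone), among them the inhibitor-of-DNA-binding genes Id3 (-0.79 ± 0.10) and Id4 (-1.59 ± 0.19) and the receptor gene Tgfbr2 (-0.71 ± 0.07). Of 24 NF-kB and cytokine genes 12 fell and 1 rose (12 and 1 adjusted over the list alone). The chemokine genes Cxcl12 (3416 ± 109 to 1481 ± 144 CPM) and Cxcl6 (-1.62 ± 0.21) were among those that fell, and the gene that rose was Cxcl10 (2.60 ± 0.26), which is also induced by interferons. Of 10 adventitial fibroblast markers 6 fell and 0 rose (6 adjusted over the list alone), including the ferritin receptor gene Scara5 (-1.44 ± 0.10) and Col14a1 (-1.93 ± 0.30). These lists had camera adjusted p = 0.00285, 1.96e-04, 0.00158 and 6.04e-04 in the order given. With an estimated correlation these became adjusted p = 0.197, 0.113, 0.197 and 0.113. The largest falls by the naming rule were Sned1 (-3.53 ± 0.38), the actin-severing protein gene Scin (-3.38 ± 0.16), the interleukin-33 receptor gene Il1rl1 (1148 ± 297 to 150.0 ± 33.9 CPM), Kazn (-2.75 ± 0.33), Kng1 (-2.72 ± 0.38), Fam169b (-2.66 ± 0.19), Akr1c15 (-2.63 ± 0.43, an aldo-keto reductase whose reads can be shared with near-identical copies) and Calcoco1 (-2.64 ± 0.80). The Calcoco1 call was lost without Control replicate 2 or 3 or any PDGF-BB library (edgeR adjusted p up to 0.0824). It was also lost with limma in every setting and with the replicate number as a block.

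Markers of the contractile and synthetic states of smooth muscle moved in both directions. In the contractile list 7 of 18 genes fell and 1 rose (7 and 1 adjusted over the list alone), and the median log2 change was -0.11. Smooth muscle actin (Acta2) went from 941 ± 176 to 651 ± 54.1 CPM (-0.53 ± 0.13, edgeR adjusted p = 0.00898), smooth muscle myosin heavy chain (Myh11) changed by -1.04 ± 0.14 and myosin light chain kinase (Mylk) by -0.99 ± 0.10. Tagln (0.28 ± 0.13, edgeR adjusted p = 0.127) and calponin 1 (Cnn1, 0.32 ± 0.15, edgeR adjusted p = 0.129) did not pass. In the synthetic list 4 of 17 genes rose and 4 fell (6 and 5 adjusted over the list alone). Osteopontin (Spp1) rose from 591 ± 33.7 to 1631 ± 158 CPM (1.46 ± 0.09) and S100a4 rose (0.75 ± 0.10), while the matrix metalloproteinase genes Mmp2 (-1.199 ± 0.15) and Mmp14 (-1.31 ± 0.13) fell, and Klf4 did not pass (-0.24 ± 0.09, edgeR adjusted p = 0.0570), though it did without Control replicate 3 (0.0343; range over 26 alternatives 0.0182 to 0.203). Camera gave adjusted p = 0.0875 for the contractile list, which became 7.31e-04 without Control replicate 2 (range over 26 alternatives 4.82e-05 to 0.827), and 0.892 for the synthetic list. Of 27 extracellular matrix genes 7 rose and 6 fell (8 and 6 adjusted over the list alone): Col3a1 went from 2199 ± 353 to 5136 ± 304 CPM, and Lama4 (-0.76 ± 0.09) and Fbln5 (-0.63 ± 0.07) fell (camera adjusted p = 0.922).

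The genes of the enzymes that PTUPB inhibits did not pass the test for PDGF-BB. Ptgs2 was at 26.1 ± 10.9 CPM in Control and 30.7 ± 8.12 CPM in PDGF-BB (0.23 ± 0.27, edgeR adjusted p = 0.538), and Ephx2 at 7.43 ± 1.51 and 7.69 ± 0.401 CPM (0.05 ± 0.17, edgeR adjusted p = 0.859). Ptgs2 did pass without Control replicate 2 (edgeR adjusted p = 0.0429) and without Control replicate 2 and PDGF-BB replicate 3 together (5.32e-04), in a range of 5.32e-04 to 0.959 over the 26 alternatives. Around them, 5 of 15 prostanoid and leukotriene genes rose and 4 fell (5 and 5 adjusted over the list alone): the leukotriene A4 hydrolase gene Lta4h (0.59 ± 0.08) and the prostaglandin reductase gene Ptgr1 (1.27 ± 0.17) rose, and the prostaglandin E synthase gene Ptges (-0.95 ± 0.19) fell. Of 7 cytochrome P450 and epoxide hydrolase genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), including a fall of Cyp1b1 (-0.47 ± 0.12). Camera adjusted p was 0.892 and 0.521 for these lists.

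In the glycolysis and hypoxia list 11 of 25 genes rose and 6 fell (12 and 7 adjusted over the list alone). The enolase gene Eno1 rose from 1163 ± 49.6 to 2026 ± 296 CPM, and the adrenomedullin gene Adm (-1.39 ± 0.11) and Pfkfb3 (-0.88 ± 0.11) fell. Of 16 NRF2 targets 7 rose and 3 fell (7 and 4 adjusted over the list alone), with Tkt at 0.84 ± 0.09 and Prdx1 at 0.79 ± 0.10. Camera adjusted p was 0.235 for glycolysis and hypoxia and 0.0759 for NRF2 targets, and both read 0.0372 without PDGF-BB replicate 2. Over the 26 alternatives they ranged from 0.0372 to 0.903 and 0.0285 to 0.587. Among immediate early and MAPK feedback genes 1 of 24 rose and 7 fell, Fos (-1.32 ± 0.24) and Dusp1 (-1.17 ± 0.14) among them (1 and 7 adjusted over the list alone). The counts of genes that rose and fell were 4 and 4 of 22 for the amino acid and ATF4 response (4 and 5 adjusted over the list alone) and 3 and 5 of 19 for endoplasmic reticulum (ER) chaperones (3 and 5). They were 5 and 2 of 14 for heat shock (6 and 2), 4 and 2 of 23 for ribosome biogenesis (2 and 0), 2 and 2 of 16 for PPAR targets and fatty acid oxidation (2 and 2), 1 and 1 of 5 for chondrogenic and osteogenic markers (2 and 2), and 0 and 0 of 12 for mitochondrially encoded genes (0 and 0). Camera adjusted p for these lists ran from 0.192 for ER chaperones to 0.963 for the amino acid list.

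Over all genes, 3714 changed with PDGF-BB (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 1942 were higher and 1772 lower, and 489 and 297 of these by at least 2-fold. In 3603 of the 3714 (97.0%) all 3 libraries of one group lay above all 3 of the other, against 44.6% of all tested genes and 10% by chance. The calls were made on these same libraries, so their separation is largely fixed by the selection and is no separate support. Scaling by library totals alone gave 2410 higher and 1350 lower genes, and limma on log2(FPKM + 1) gave 2427 and 1283, so the balance of rises and falls depended on the scaling. Without Control replicate 2 and PDGF-BB replicate 3, 4265 genes changed.

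**Figure D1:**
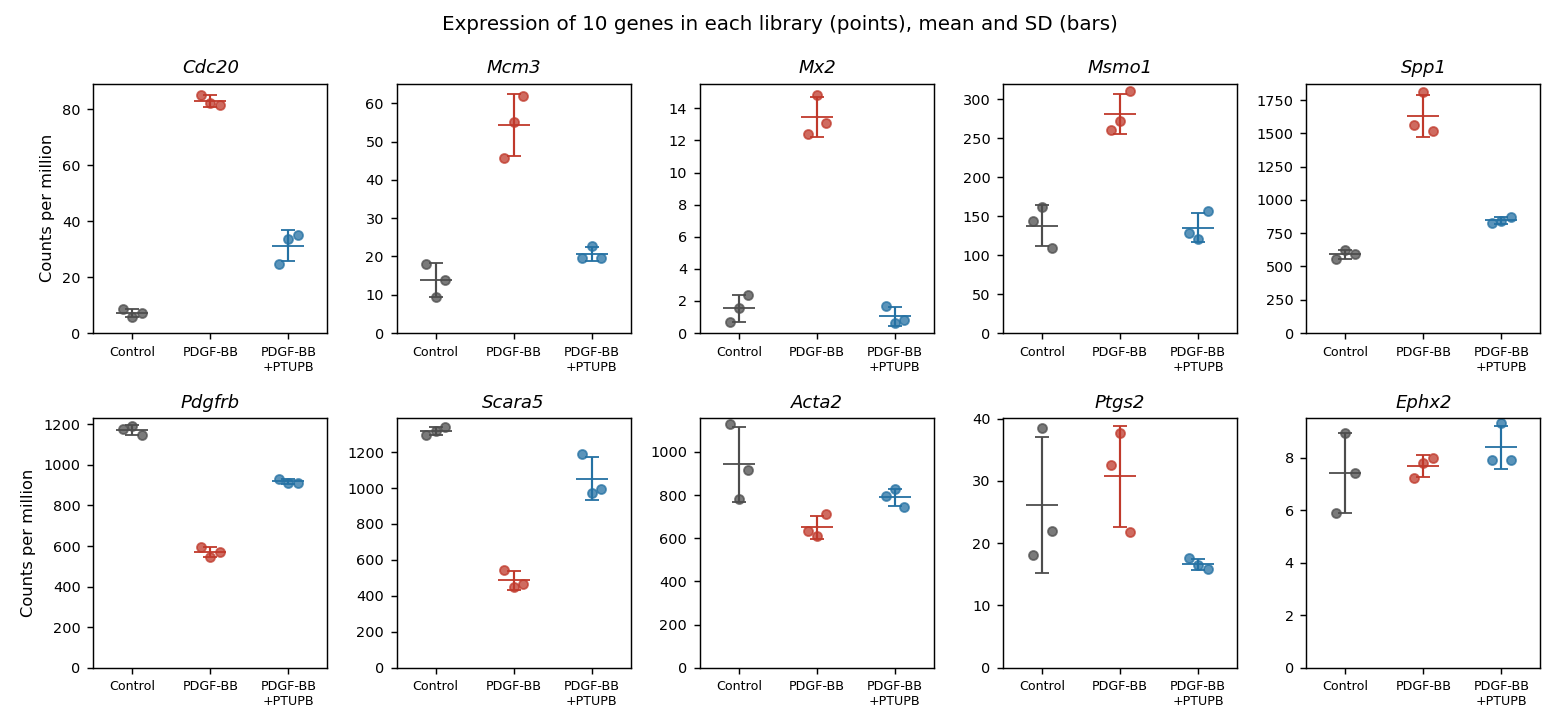
Levels of 10 genes in each library, in CPM on a linear axis, by group; points are the 3 libraries of a group and bars the mean ± SD. Cdc20 has means of 7.16 in Control, 82.9 in PDGF-BB and 31.3 in PDGF-BB+PTUPB, whereas Msmo1 has 138, 281 and 135.

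The comparison of PDGF-BB+PTUPB with PDGF-BB asks what the compound changed in growth factor-treated cells. Cell cycle genes fell. Cdc20 went from 82.9 ± 2.000 to 31.3 ± 5.66 CPM (-1.41 ± 0.15, edgeR adjusted p = 5.76e-04), and 21 of 29 G2/M genes fell with 0 rising (26 adjusted over the list alone). Among them were the survivin gene Birc5 (-1.61 ± 0.17), Cdca8 (-1.34 ± 0.16) and Cdc25c (-0.91 ± 0.11). The proliferation marker Mki67, at 129.9 ± 65.9 and 73.6 ± 4.70 CPM, did not pass (-0.82 ± 0.39, edgeR adjusted p = 0.174). It passed without PDGF-BB replicate 3 (0.0159), in a range of 1.87e-04 to 0.433 over the 26 alternatives. Of 29 S phase genes 18 fell and 0 rose (23 adjusted over the list alone). These included the replicative helicase genes Mcm3 (54.3 ± 8.19 to 20.6 ± 1.81 CPM, -1.39 ± 0.20), Mcm6 (-1.29 ± 0.18) and Mcm7 (-0.83 ± 0.11), and Tyms (-1.06 ± 0.13). In the G1 list 6 of 15 genes fell and 1 rose (6 and 2 adjusted over the list alone). Ccnd1 changed by -0.69 ± 0.14, and the inhibitor Cdkn1a moved the same way (-0.48 ± 0.09), with Gas1 (1.26 ± 0.22) the gene that rose. Camera gave adjusted p = 8.96e-22 for G2/M, 5.59e-15 for S phase and 0.0435 for the G1 list, and 0.145 was the adjusted p of all 3 with an estimated correlation. The G1 call was lost without Control replicate 1 (camera adjusted p = 0.0528), PDGF-BB replicate 1 (0.0742), PDGF-BB replicate 2 (0.0704), PDGF-BB+PTUPB replicate 2 (0.0514) or PDGF-BB+PTUPB replicate 3 (0.122), and the range over the 26 alternatives was 0.0171 to 0.145.

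Interferon response and lipid synthesis genes fell too. Of 23 interferon response genes 14 fell and 0 rose (16 adjusted over the list alone). Irf7 fell to 8.87 ± 0.523 CPM (-1.69 ± 0.15, edgeR adjusted p = 5.62e-04), and Mx2 (-3.71 ± 0.41), Rsad2 (-2.43 ± 0.34) and Usp18 (-1.41 ± 0.20) fell with it. Of 23 cholesterol synthesis genes 19 fell and 0 rose (20 adjusted over the list alone). Msmo1 went to 135 ± 18.6 CPM (-1.06 ± 0.15), and the squalene epoxidase gene Sqle from 157 ± 10.9 to 96.6 ± 4.38 CPM (-0.70 ± 0.09). In the fatty acid synthesis list 8 of 14 genes fell and 1 rose (10 and 1 adjusted over the list alone): the stearoyl-CoA desaturase gene Scd changed by -1.53 ± 0.22, the ATP citrate lyase gene Acly by -0.56 ± 0.08 and the rising Gpam by 1.18 ± 0.13. Of 18 p53 targets 5 fell and 0 rose (6 adjusted over the list alone), including Mdm2 (-0.59 ± 0.09) and Plk2 (-0.69 ± 0.14). By camera, adjusted p was 3.58e-11, 5.45e-16, 4.67e-05 and 0.00720 for these lists in the order given, and 0.135 was the adjusted p of each with an estimated correlation. All 14 interferon genes and all 5 p53 targets that fell were genes that PDGF-BB had raised, as were 15 of the 19 cholesterol genes, 18 of 18 S phase genes and 21 of 21 G2/M genes. Over all genes, 1038 of the 1121 that fell had been raised by PDGF-BB, and both comparisons use the PDGF-BB libraries. The overlap is therefore not particular to these lists.

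The groups that PDGF-BB lowered moved upwards. Pdgfrb rose from 570.2 ± 24.9 to 919 ± 11.1 CPM (0.69 ± 0.07, edgeR adjusted p = 5.62e-04), and in its list 4 of 14 genes rose and 1 fell (7 and 1 adjusted over the list alone). Pdgfra (0.61 ± 0.13) and Vegfa (0.56 ± 0.07) were among the rises and Pdgfc (-0.68 ± 0.10) was the fall. Of 20 TGF-beta and BMP targets 10 rose and 1 fell (11 and 1 adjusted over the list alone), with Tgfbr2 at 0.41 ± 0.07, Id1 at 0.68 ± 0.12 and Smad7 at 0.47 ± 0.10. Of 24 NF-kB and cytokine genes 9 rose and 2 fell (10 and 2 adjusted over the list alone): Cxcl12 (0.79 ± 0.10) and Ccl7 (0.56 ± 0.11) rose, and Cxcl10 fell from 13.1 ± 2.998 to 2.32 ± 0.0784 CPM (-2.49 ± 0.26). Of 10 adventitial fibroblast markers 4 rose and 0 fell (6 adjusted over the list alone), including Scara5 (1.11 ± 0.10). The lists had camera adjusted p = 0.00720, 1.81e-04, 0.00528 and 1.33e-04 in this order. With an estimated correlation these became adjusted p = 0.234, 0.135, 0.235 and 0.135. By the naming rule, the largest rises included Sned1 (2.55 ± 0.38), Scin (2.37 ± 0.16), Il1rl1 (2.30 ± 0.32), Fam180a (2.22 ± 0.18), Fam169b (1.98 ± 0.20) and the cysteine dioxygenase gene Cdo1 (1.92 ± 0.16). The largest falls beyond Mx2 and Cxcl10 included the antiviral Oas1a (-2.47 ± 0.48), the protease genes Mmp10 (-1.85 ± 0.35) and Adamts8 (-1.83 ± 0.20), and Raver2 (-1.83 ± 0.28). The naming rule also gave rises of Akr1c15 (2.03 ± 0.43) and Serpina12 (1.99 ± 0.55) and falls of Anos1, at 0 counts with PTUPB, and the class I histocompatibility gene RT1-T24-1 (-1.86 ± 0.45). Of these, the Serpina12 call was lost without PDGF-BB replicate 2 or 3 or any PDGF-BB+PTUPB library (edgeR adjusted p up to 0.122), the Anos1 call without PDGF-BB replicate 1 or 2 or any PDGF-BB+PTUPB library (up to 0.0783), and the RT1-T24-1 call without PDGF-BB replicate 1 or PDGF-BB+PTUPB replicate 1 or 2 (up to 0.0699).

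In the contractile list 4 of 18 genes rose with PTUPB and 1 fell (4 and 1 adjusted over the list alone). Mylk rose (0.71 ± 0.10). Myh11 also rose (0.54 ± 0.14, edgeR adjusted p = 0.0210), a call lost without PDGF-BB replicate 2 or 3 or PDGF-BB+PTUPB replicate 1 or 2 (up to 0.0839). The rise of Itga8 was lost without PDGF-BB replicate 3 or PDGF-BB+PTUPB replicate 1 or 2 (edgeR adjusted p up to 0.117). Acta2 (789 ± 40.7 CPM, 0.28 ± 0.13, edgeR adjusted p = 0.158), Tagln (-0.01 ± 0.13), Cnn1 (-0.24 ± 0.15) and Klf4 (-0.04 ± 0.09, edgeR adjusted p = 0.774) did not pass. In the synthetic list 3 of 17 genes rose and 3 fell (3 and 3 adjusted over the list alone). Spp1 fell to 846 ± 25.2 CPM (-0.95 ± 0.09, edgeR adjusted p = 5.62e-04), stromelysin-1 (Mmp3) fell (-1.60 ± 0.32), and Mmp14 (0.66 ± 0.12) and Mmp2 (0.69 ± 0.14) rose. Of 27 extracellular matrix genes 6 rose and 4 fell (8 and 7 adjusted over the list alone), with Col3a1 at -0.87 ± 0.15 and Lama4 at 0.60 ± 0.09. Camera adjusted p was 0.403, 0.753 and 0.753 for the 3 lists.

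Of the genes of PTUPB's targets, Ephx2 was at 8.40 ± 0.809 CPM with PTUPB (0.13 ± 0.17, edgeR adjusted p = 0.637). Ptgs2 was at 16.6 ± 0.888 CPM, a log2 change of -0.89 ± 0.27 with an edgeR adjusted p of 0.0470. That call was lost without Control replicate 3 (edgeR adjusted p = 0.0608), PDGF-BB replicate 1 (0.113), PDGF-BB replicate 2 (0.131), PDGF-BB+PTUPB replicate 1 (0.113), replicate 2 (0.123) or replicate 3 (0.130), and with limma on log2(FPKM + 1). Over the 26 alternatives it ranged from 1.81e-04 to 0.131. Of 15 prostanoid and leukotriene genes 1 rose and 3 fell (2 and 4 adjusted over the list alone), Lta4h at -0.38 ± 0.08, and of 7 cytochrome P450 and epoxide hydrolase genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), Cyp1b1 at 0.61 ± 0.12 (camera adjusted p = 0.865 and 0.285). Without PDGF-BB+PTUPB replicate 1 the rise of Ptger1 and the fall of Ptgr1 were lost, as was the Ptgs2 call. In fits that leave out 1 library, the Cyp4f6 call was lost in 6 and the Por call in 2 (edgeR adjusted p up to 0.142 and 0.0666).

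Glycolysis and hypoxia genes split, 5 of 25 rising and 9 falling (6 and 9 adjusted over the list alone): Pfkp fell (-0.54 ± 0.10) and Adm rose (1.14 ± 0.11). The haem oxygenase gene Hmox1 rose from 90.8 ± 7.91 to 210.2 ± 11.4 CPM (1.21 ± 0.25) while Prdx1 (-0.48 ± 0.10) and Tkt (-0.44 ± 0.09) fell, among 2 rises and 4 falls in 16 NRF2 targets (3 and 6 adjusted over the list alone). Rises and falls numbered 4 and 2 of 22 for the amino acid and ATF4 response (4 and 3 adjusted over the list alone), 2 and 2 of 24 for immediate early and MAPK feedback genes (5 and 2) and 3 and 3 of 19 for ER chaperones (3 and 5). They numbered 1 and 3 of 14 for heat shock (2 and 6), 0 and 1 of 23 for ribosome biogenesis (0 and 1), and 0 and 0 for PPAR targets, for chondrogenic and osteogenic markers and for mitochondrially encoded genes (0 and 0 for each). Camera adjusted p for the lists of this paragraph ran from 0.140 for ribosome biogenesis, which became 0.0401 without PDGF-BB replicate 2 (range over 26 alternatives 0.0401 to 0.649), to 0.903 for PPAR targets.

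Over all genes 2048 changed with PTUPB, 927 higher and 1121 lower (edgeR, adjusted p under 0.05), and 113 and 189 of these by at least 2-fold. In 2044 of the 2048 (99.8%) the libraries of the groups did not overlap, against 40.7% of all tested genes and 10% by chance. Here too the selection of calls largely fixes their separation. The count fell to 1002, 1109 and 1331 without PDGF-BB+PTUPB replicates 1, 2 and 3, and library totals alone split the calls into 759 higher and 1414 lower, limma on log2(FPKM + 1) into 728 and 1419. Without Control replicate 2 and PDGF-BB replicate 3, 2818 genes changed.

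**Figure D2:**
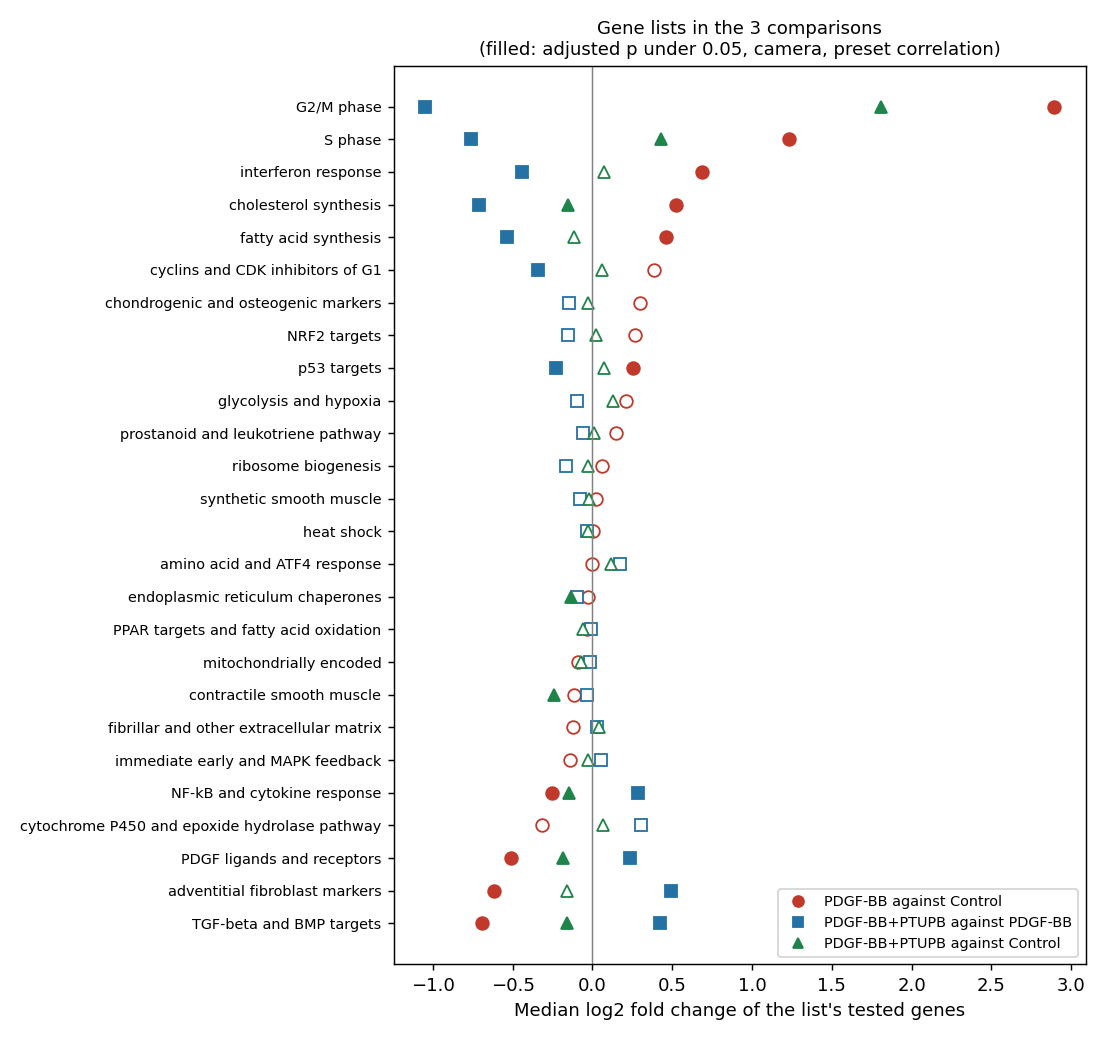
Median log2 fold change of the tested genes of each of 26 gene lists (horizontal axis) in the 3 comparisons; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. The G2/M list has medians of 2.89 for PDGF-BB against Control, -1.05 for PDGF-BB+PTUPB against PDGF-BB and 1.81 for PDGF-BB+PTUPB against Control, and the cholesterol list 0.53, -0.71 and -0.15.

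The comparison of PDGF-BB+PTUPB with Control shows which differences from untreated cells remained with the compound. Mitotic genes stayed higher. Cdc20 stood at 31.3 ± 5.66 CPM against 7.16 ± 1.38 in Control (2.13 ± 0.16, edgeR adjusted p = 4.18e-04), Kif20a at 96.1 ± 30.5 against 19.6 ± 8.25 CPM, and cyclin B1 (Ccnb1) at 39.7 ± 10.9 against 8.22 ± 2.95 CPM. In the G2/M list 21 of 29 genes were higher and 0 lower (29 adjusted over the list alone), and these were the same 21 that PTUPB had lowered relative to PDGF-BB. Of 29 S phase genes 5 were higher and 0 lower (13 adjusted over the list alone), among them the ribonucleotide reductase gene Rrm2 (1.202 ± 0.17) and Tyms (0.88 ± 0.13). The S phase calls of Mcm10 and Rrm1 were lost without Control replicate 3 or PDGF-BB+PTUPB replicate 2 or 3 (edgeR adjusted p up to 0.0723 and 0.112). Other large differences were in Ube2t (2.62 ± 0.34), Cenpt (2.34 ± 0.24), Knstrn (2.28 ± 0.16), Troap (2.24 ± 0.23), Traip (2.23 ± 0.27) and Pttg1 (2.21 ± 0.25). Camera gave adjusted p = 6.44e-105 for the G2/M list, and 0.0361 with an estimated correlation, the only list call to hold there. The S phase list had adjusted p = 4.23e-14, and 0.433 with an estimated correlation.

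Few genes were called lower than in Control, 35 against 212 higher. Without Control replicate 2 and PDGF-BB replicate 3 the calls were 695 lower and 650 higher. Missing calls are weak evidence here, as 43 of 66 simulated 2-fold changes were recovered in this comparison. Scin was at 89.7 ± 10.2 against 181 ± 33.4 CPM (-1.01 ± 0.14, edgeR adjusted p = 0.00542). The other 7 of the 8 largest falls by the naming rule were C4bpa (-1.29 ± 0.23), the BMP target Id2 (-1.24 ± 0.23), Chi3l1 (-1.204 ± 0.24), Sfrp2 (-1.18 ± 0.22), Zmynd19 (-1.07 ± 0.18), the chemokine gene Cx3cl1 (-1.03 ± 0.22) and the growth factor receptor gene Fgfr2 (-0.76 ± 0.16). Each of these calls was lost without PDGF-BB+PTUPB replicate 2 and without PDGF-BB+PTUPB replicate 3. Calls were also lost without Control replicate 3 for Chi3l1, Zmynd19, Cx3cl1 and Fgfr2, Control replicate 2 for Chi3l1 and Cx3cl1, Control replicate 1 for Fgfr2, and PDGF-BB replicate 1 or 2 or PDGF-BB+PTUPB replicate 1 for Cx3cl1 and Fgfr2. Without 1 library, edgeR adjusted p of the 7 genes was up to 0.0995, 0.124, 0.147, 0.132, 0.0799, 0.207 and 0.201 in the order given. Pdgfrb stood at 919 ± 11.1 CPM (-0.35 ± 0.07, edgeR adjusted p = 0.0257) and Spp1 at 846 ± 25.2 CPM (0.52 ± 0.09, 0.0136). The Spp1 call was lost without Control replicate 3 or PDGF-BB+PTUPB replicate 2 or 3 (edgeR adjusted p up to 0.0933), and the Pdgfrb call without Control replicate 1 or 3, PDGF-BB replicate 1 or any PDGF-BB+PTUPB library (up to 0.150). Acta2 (-0.25 ± 0.13, edgeR adjusted p = 0.412), Myh11 (-0.50 ± 0.13, 0.105), Tagln (0.27 ± 0.13, 0.407), Cnn1 (0.08 ± 0.15, 0.873), Klf4 (-0.28 ± 0.09, 0.167), Ccnd1 (0.09 ± 0.14, 0.847), Mki67 (1.31 ± 0.40, 0.167), Ptgs2 (-0.66 ± 0.27, 0.324) and Ephx2 (0.17 ± 0.17, 0.717) did not pass. Mki67 passed without PDGF-BB replicate 3 (edgeR adjusted p = 0.0252) and Myh11 without Control replicate 2 (0.0416), and the ranges over 26 alternatives were 0.00180 to 0.454 and 0.00921 to 0.374.

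In the remaining lists few single genes were called against Control, which does not show that these lists were at the Control level. Among 19 ER chaperones 0 genes were higher and 1 lower (0 and 3 adjusted over the list alone), with a median log2 change of -0.13 (camera adjusted p = 7.74e-05, and 0.302 with an estimated correlation). The lower gene, Hyou1, was not called without Control replicate 3 or PDGF-BB+PTUPB replicate 2 or 3 (edgeR adjusted p up to 0.0755). Small shifts of the whole list passed for NF-kB and cytokine genes (median -0.15, camera adjusted p = 0.0335), contractile genes (-0.24, 0.0426), TGF-beta and BMP targets (-0.16, 0.0426), PDGF ligands and receptors (-0.18, 0.0429) and cholesterol synthesis (-0.15, 0.0482). With an estimated correlation their adjusted p rose to 0.606 for the NF-kB, TGF-beta and PDGF lists and 0.798 for the contractile and cholesterol lists. Single genes higher and lower numbered 0 and 1 in the NF-kB list (1 and 5 adjusted over the list alone), 0 and 1 in the TGF-beta list (1 and 4), 0 and 1 in the PDGF list (1 and 2), 0 and 0 in the contractile list (0 and 2) and 0 and 0 in the cholesterol list (0 and 0). The NF-kB call was lost without Control replicate 2 (camera adjusted p = 0.108), Control replicate 3 (0.0862) or PDGF-BB+PTUPB replicate 3 (0.0934). The contractile call was lost without Control replicate 1 (camera adjusted p = 0.542), Control replicate 3 (0.190), PDGF-BB replicate 2 (0.0509), PDGF-BB+PTUPB replicate 1 (0.0612) or replicate 3 (0.0934). The TGF-beta call went without Control replicate 1 (camera adjusted p = 0.289) or PDGF-BB+PTUPB replicate 1 (0.114). The PDGF call went without Control replicate 1 (camera adjusted p = 0.209), Control replicate 3 (0.0649), PDGF-BB replicate 2 (0.0530), PDGF-BB+PTUPB replicate 2 (0.0703) or replicate 3 (0.0859). The cholesterol call went without Control replicate 1 (camera adjusted p = 0.355), Control replicate 2 (0.432), PDGF-BB replicate 1 (0.05004), 2 (0.0530) or 3 (0.0620) or PDGF-BB+PTUPB replicate 2 (0.412). Over the 26 alternatives the adjusted p of these 5 lists ranged from 8.24e-04 to 0.606, 3.32e-08 to 0.798, 0.00129 to 0.606, 0.00399 to 0.606 and 7.19e-06 to 0.798 in this order.

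None of the other tested lists passed in this comparison. Of 17 synthetic genes 3 were higher and 1 lower (3 and 4 adjusted over the list alone). The calls of Spp1, S100a4, Vim and Mmp14 were each lost without PDGF-BB+PTUPB replicate 2 and without replicate 3. Without 1 library their edgeR adjusted p was up to 0.188. In addition 1 of 15 G1 genes, 1 of 16 NRF2 targets and 1 of 14 heat shock genes were higher with 0 lower (1, 2 and 1 higher adjusted over the list alone). The G1 call (Cdkn2c) and the NRF2 call (Nqo1) were each lost in 7 fits that leave out 1 library (edgeR adjusted p up to 0.224 and 0.186). By edgeR 0 genes were higher or lower in the interferon, fatty acid, p53, extracellular matrix, prostanoid, cytochrome P450, immediate early, PPAR, glycolysis, amino acid, ribosome biogenesis, adventitial fibroblast, chondrogenic and osteogenic, and mitochondrially encoded lists. Adjusted over the list alone, these lists also had 0 calls, except 1 higher and 1 lower fibroblast marker and 0 higher and 1 lower chondrogenic and osteogenic marker. The heat shock gene was Hsp90aa1 (2.06 ± 0.29), whose counts are uncertain because reads can be shared with near-identical copies. Camera adjusted p for the lists that did not pass ran from 0.0834 for NRF2 targets to 0.898 for the synthetic list. The NRF2 list reached camera adjusted p = 0.0151 without Control replicate 2 and 0.0355 without PDGF-BB replicate 3, and the mitochondrial list 0.0263 without Control replicate 3, with ranges of 0.00294 to 0.798 and 0.0102 to 0.913 over the 26 alternatives.

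Over all genes 247 differed from Control, 212 higher and 35 lower (edgeR, adjusted p under 0.05), and 128 and 9 of these by at least 2-fold; 239 were also PDGF-BB calls in the same direction. The comparisons share the Control libraries, which by itself makes their changes agree: the median correlation of log2 changes was 0.499 in 20 simulations of unchanged groups, against 0.732 observed, and the median covariance 0.0275 against 0.163. All 247 had groups that did not overlap, against 21.5% of all tested genes and 10% by chance, a separation again largely fixed by the selection of calls. The count was 126 without Control replicate 3, 164 without PDGF-BB replicate 1, 94 without PDGF-BB+PTUPB replicate 2, 93 without PDGF-BB+PTUPB replicate 3 and 444 with DESeq2 (330 higher, 114 lower). Without Control replicate 2 and PDGF-BB replicate 3 it rose to 1345 (650 higher and 695 lower), and these held all 247. Leaving out the libraries that stood furthest from their groups by itself lowers the spread, so this rise is no independent support.

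Set side by side, the comparisons with PDGF-BB in common asked how far PTUPB opposed the growth factor. No group received PTUPB alone, so opposed calls may also come from an effect of PTUPB that does not depend on PDGF-BB. Of the 3714 PDGF-BB calls 1880 (50.6%) were called in the opposite direction with PTUPB, 1038 of them genes such as Cdc20, Irf7 and Msmo1 that had risen and 842 genes such as Pdgfrb, Scara5 and Scin that had fallen. In the same direction 0 genes were called by edgeR, 0 by DESeq2, 0 by limma on log2(FPKM + 1) and 2 at an unadjusted p under 0.05 in both comparisons. Leaving out Control replicate 1 or 2 gave 1 and 2 such edgeR calls. Independent lists of these sizes would share 341 genes in opposite directions (194 and 147) and 338 in the same direction. Of the PTUPB calls 91.8% were PDGF-BB calls, and 98.9% of PDGF-BB calls had a PTUPB log2 change of the opposite sign. The comparisons share the PDGF-BB libraries, which by itself makes their changes oppose: over 20 simulations of unchanged groups the median correlation of log2 changes was -0.503, against -0.850 observed, and the covariance was -0.0268 (-0.0308 to -0.0237) against -0.245, a difference of -0.218. The PDGF-BB group was not split so that each comparison had its own PDGF-BB libraries, and genes were simulated independently of one another. Part of the excess may therefore come from the shared libraries. The opposed count was 958 without PDGF-BB+PTUPB replicate 1 and 1066 without PDGF-BB+PTUPB replicate 2, and 2359 without Control replicate 2 and PDGF-BB replicate 3.

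The share of the PDGF-BB change left with PTUPB was a slope through 0, corrected for the noise of the shared Control libraries. It was 0.388 over all genes, where 1 means the change was kept in full and 0 that it was gone. Its delete-one-library range was 0.359 to 0.433. The G2/M list kept 0.629 (0.591 to 0.668), and the S phase list 0.449 (0.369 to 0.507). For interferon response genes it was -0.00960 (-0.180 to 0.0845) and for cholesterol synthesis -0.177 (-0.349 to -0.0799). A value below 0 would mean that genes on balance ended on the other side of Control, but the jackknife SE was 0.193 and 0.231 for these 2 lists, so neither differs from 0 by more than 1 SE and no overshoot is shown (SE 0.0613 for all genes, 0.0790 for G2/M and 0.110 for S phase). Extracellular matrix genes kept 0.243 (0.167 to 0.299), contractile genes 0.342 (0.244 to 0.469), TGF-beta and BMP targets 0.479 (0.459 to 0.518) and PDGF ligands and receptors 0.332 (0.282 to 0.375). PPAR targets and fatty acid oxidation genes were at 0.639 (0.567 to 0.806), but only 2 of 16 had risen and 2 fallen with PDGF-BB. Heat shock genes were at 0.523 (0.454 to 0.635). Genes with large changes weigh most in the slope, and Hsp90aa1 stood 6.96-fold above Control in PDGF-BB and 4.18-fold in PDGF-BB+PTUPB. Counts of Hsp90aa1 are uncertain, and the share without it was not computed. Fatty acid synthesis genes were at -0.372 (-0.876 to 0.0159). The order of lists depended on the scale. In linear weights (the position of a gene between the CPM means of Control, 0, and PDGF-BB, 1, a test chosen after the results were seen), medians over called genes were 0.391 (0.320 to 0.422) for the G2/M list against 0.320 (0.291 to 0.360) for all PDGF-BB calls, ranges that overlap, 0.281 for S phase, 0.440 for contractile genes and 0.369 for TGF-beta and BMP targets, while interferon (0.0634) and cholesterol genes (-0.172) stayed low. Called different from both other groups, and between them, were 191 genes, with median log2 changes from Control of 2.16 in PDGF-BB and 1.16 in PDGF-BB+PTUPB. Outside both groups were 7 genes, named here after their values were seen. Their edgeR adjusted p against Control ran from 0.00755 (Il1r2) to 0.0489 (Gsta1), with most of them near the threshold of 0.05. Whether these calls hold without 1 library was not examined. Against Control, PTUPB gave Angptl7 (1.96 ± 0.39), AABR07011951.1 (2.87 ± 0.62), the decoy interleukin-1 receptor Il1r2 (0.67 ± 0.10), Gsta1 (0.58 ± 0.13), Cd180 (0.54 ± 0.10) and the circadian gene Per2 (0.41 ± 0.09) above, and LOC687780 (-0.70 ± 0.15) below. Without Control replicate 2 and PDGF-BB replicate 3 the numbers were 54 above both groups and 34 below.

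**Figure D3:**
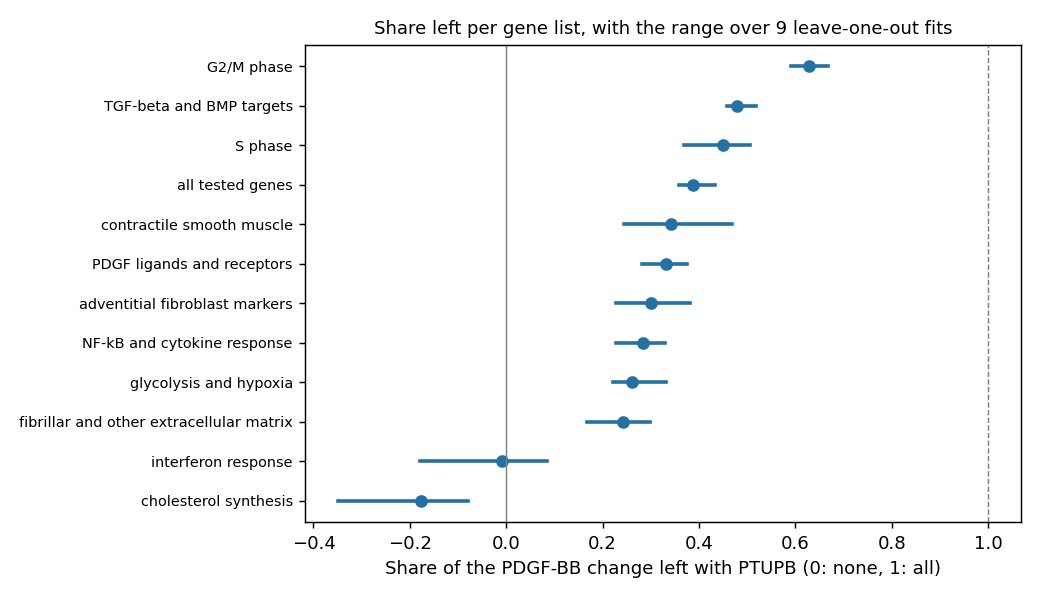
Share of the PDGF-BB change left with PTUPB (horizontal axis, no unit) for all tested genes and for some of the gene lists. Points are the estimate over all 9 libraries and bars the range over fits that each leave out 1 library. Lists not drawn include PPAR targets and fatty acid oxidation (0.639), heat shock (0.523) and fatty acid synthesis (-0.372). The G2/M list lies at 0.629 and the interferon and cholesterol lists at -0.00960 and -0.177.

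Most endothelial, macrophage, Schwann cell, and chondrogenic and osteogenic markers were near background, whereas adventitial fibroblast markers were not. Endothelial genes were below an FPKM of 1 in all 9 libraries for 11 of 13 markers, macrophage genes for 12 of 15, Schwann cell genes for 5 of 7, pericyte genes for 3 of 7, and chondrogenic and osteogenic genes for 8 of 13. The highest FPKM in any library was 17.1 for endothelial markers (Egfl7), 19.6 for macrophage markers (Cd14), 16.6 for Schwann cell markers (Ncam1), 6.59 for pericyte markers (Cspg4) and 17.5 for chondrogenic and osteogenic markers (Bmp2). Adventitial fibroblast markers were abundant, with 2 of 12 below 1 and Lum reaching an FPKM of 979. Whether the cultures held fibroblasts was not tested. Lists with fewer than 5 tested genes had no list test: with PDGF-BB 1 of 2 endothelial markers rose (1 adjusted over the list alone), 1 of 3 macrophage markers fell (Lyz2, -1.80 ± 0.24; 2 adjusted over the list alone), 1 of 4 pericyte markers rose (Cspg4, 1.01 ± 0.20) and 2 fell (1 and 2 adjusted over the list alone), and of the Schwann cell markers Ncam1 rose (0.87 ± 0.17) and Mbp fell (-1.86 ± 0.31). The endothelial rise (Flt1) was lost in 7 of 9 fits that leave out 1 library, and the pericyte falls in 3 (Kcnj8) and 6 (Abcc9), with edgeR adjusted p up to 0.105, 0.0720 and 0.133. With PTUPB against PDGF-BB 1 of 2 endothelial and 2 of 3 macrophage markers rose (Lyz2, 1.61 ± 0.24), and 0 of 4 pericyte markers changed (1, 2 and, for pericytes, 0 rises and 1 fall adjusted over the list alone). The endothelial rise (Egfl7) was lost with DESeq2 and in 7 of the 9 fits, and the macrophage rise of Cd14 in 5, with edgeR adjusted p up to 0.164 and 0.0990. Mbp rose (1.13 ± 0.32) and Ncam1 fell (-0.56 ± 0.17) with PTUPB, calls that were both lost without PDGF-BB replicate 1 or PDGF-BB+PTUPB replicate 1 or 2, for Mbp also without PDGF-BB replicate 3 and for Ncam1 without Control replicate 3 or PDGF-BB replicate 2 (edgeR adjusted p up to 0.130 and 0.149). Against Control 0 genes of these lists differed, and 1 endothelial marker did when adjusted over the list alone.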

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

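Chosen after the data were seen were the length offset, the thinned counts, library totals as the only scaling, covariances about the means and the fit without Control replicate 2 and PDGF-BB replicate 3. No call of a named gene or a gene list reversed its direction. Over all alternatives, named genes kept their call or lack of one in 7972 results, lost it in 364 and gained it in 48, and gene lists in 1925, 72 and 28. List calls depended on the correlation. With an estimated correlation 0 of 26 lists passed for PDGF-BB against Control (10 at the preset), 0 for PDGF-BB+PTUPB against PDGF-BB (11) and 1 for PDGF-BB+PTUPB against Control (8). The preset takes genes of a list as nearly independent, which the estimate does not. For PDGF-BB against Control, fry adjusted p was 1.45e-04 for the G2/M, interferon and G1 lists, 0.00621 for ER chaperones and 0.174 for the contractile list. For PDGF-BB+PTUPB against PDGF-BB it was 0.0104 for G2/M and 0.00301 for cholesterol synthesis. For PDGF-BB+PTUPB against Control it was 0.00758 for G2/M and 0.0833 for S phase. As fry does not set a list against other genes, it answers a different question from camera. DESeq2 called 444 genes in PDGF-BB+PTUPB against Control (247 with edgeR); the cause was not tested. Without Control replicate 2 and PDGF-BB replicate 3 there were 2818 calls in PDGF-BB+PTUPB against PDGF-BB and 2359 opposed genes. In PDGF-BB+PTUPB against Control there were 1345 calls (650 higher and 695 lower, against 212 and 35). Leaving out the libraries furthest from their groups lowers the spread that all comparisons share, so more calls may follow from that choice alone. The cause was not tested. Leaving out 1 library at a time gave 2770 to 3902 genes for PDGF-BB against Control, 1002 to 2463 for PDGF-BB+PTUPB against PDGF-BB, 93 to 340 for PDGF-BB+PTUPB against Control, 10 to 12, 10 to 11 and 4 to 8 lists in the same order, 958 to 2110 opposed genes, and a share left of 0.359 to 0.433. The share left of the interferon list changed sign, between -0.180 and 0.0845. The list count of PDGF-BB+PTUPB against Control was 4 without Control replicate 1, 5 without PDGF-BB replicate 2 and 5 without PDGF-BB+PTUPB replicate 3. A fit that leaves 2 libraries in a group assumes that these vary like the others. Thinned to the smallest total, calls numbered 3613, 2031 and 236, against 3714, 2048 and 247.

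With the replicate number as a replicate block, 3294, 1602 and 168 genes were called, 10, 10 and 7 lists passed, 1497 genes were opposed and the share left was 0.394. The numbers were not used as pairs because deviations of libraries with the same number correlated between -0.361 and 0.308, over 0.1 in 3 of 9 pairs.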

Other observations

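The search of Gene Ontology terms, the tests of mixing, of compression and of length bias, and the per-library tests of abundant genes were chosen after the results were seen. Genes of mRNA splicing, which join the exons of transcripts, rose with PDGF-BB (52 of 145 rose, 3 fell, camera adjusted p = 2.36e-04) and fell with PTUPB against PDGF-BB (0 rose, 43 fell, 2.41e-06), calls that were lost with an estimated correlation (adjusted p = 0.474 and 0.525). Hnrnpa1, a splicing repressor, changed by 1.64 ± 0.13 and -1.11 ± 0.13 and Lsm4, of the U6 particle, by 1.42 ± 0.13 and -0.92 ± 0.13 (log2 ± SE, n = 3 per group). Proteasome genes, listed under ubiquitin-independent catabolism, did likewise (16 of 24 rose and 1 fell with PDGF-BB, 5.02e-04; 0 rose and 14 fell with PTUPB, 3.50e-05; lost with an estimated correlation, 0.543 and 0.619), with Psma1 at 0.68 ± 0.10 and -0.50 ± 0.10 and Psmb7 at 0.66 ± 0.11 and -0.51 ± 0.11.

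Genes of lysosome organization fell with PDGF-BB (0 rose and 15 of 32 fell, camera adjusted p = 0.00211) and rose with PTUPB (7 rose, 0 fell, 0.00184), calls lost with an estimated correlation (0.413 and 0.525), among them the iduronidase gene Idua (-0.84 ± 0.08 and 0.64 ± 0.08). Cell adhesion genes of the cadherin and protocadherin type moved the same way (5 rose and 23 of 53 fell, 0.00267; 10 rose and 2 fell, 0.0418; lost with an estimated correlation, 0.513 and 0.666), with N-cadherin (Cdh2) at -0.99 ± 0.10 and 0.71 ± 0.10, and the term also passed against Control with 0 genes called (0.00382; 0.709 with an estimated correlation). In all, 90, 84 and 47 of 869 terms passed in PDGF-BB against Control, PDGF-BB+PTUPB against PDGF-BB and PDGF-BB+PTUPB against Control, and with an estimated correlation 0 passed in each.

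PDGF-BB+PTUPB libraries lay between Control and PDGF-BB libraries. A mixture of Control and PDGF-BB RNA in a single proportion would give every gene the same linear weight, but the median weight of the cholesterol list was lower than that of the G2/M list by a difference of -0.564. Lower depth of the PDGF-BB libraries is argued against by the 1849 genes still opposed after thinning to the smallest total. Noise of the shared PDGF-BB libraries that is independent between genes, as the whole cause, is argued against by the covariance. It was -0.245, against a lowest simulated value of -0.0308. Deviations that many genes of the PDGF-BB libraries share were not simulated, so they are not argued against. An action of PTUPB on the PDGF-BB response may account for the position, a hypothesis. No group received PTUPB without PDGF-BB, so an effect of PTUPB that does not depend on PDGF-BB cannot be told apart from such an action. With 10 splits of 6 libraries into 3 and 3 the splits are too few for a share under 0.05: a result as large came from 1 of 10 splits in each comparison, the real 1, with 3714, 2048 and 247 genes against 0, 1 and 1 in the highest other split.

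G2/M genes kept more of the PDGF-BB change than interferon and cholesterol genes. Compression of large changes on the log2 scale, as the whole cause of this difference, is argued against by linear weights, where the G2/M median was at lowest 0.320 over fits that leave out 1 library, above the highest values of the interferon (0.150) and cholesterol lists (-0.0468). It is not argued against for G2/M genes set against other changed genes: the weight of all PDGF-BB calls was 0.320 (0.291 to 0.360), of calls that fell 0.368, of TGF-beta and BMP targets 0.369 and of contractile genes 0.440, beside 0.391 (0.320 to 0.422) for G2/M. A single library is argued against by the smallest difference in share left over the same fits, 0.542. PTUPB may therefore act more fully on cholesterol synthesis and interferon genes than on G2/M genes, a hypothesis found and tested on the same data. Whether fewer cells divide, or each dividing cell expresses less, was not tested.

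Control replicate 2 and PDGF-BB replicate 3 stood apart from their groups. Length bias as the whole cause is argued against by a distance (root mean square, log2) of at least 0.387 after a length correction, against at most 0.347 in the other 7 libraries, and at least 0.404 before it. The 10 most abundant genes took 8.51% of counts in Control replicate 2 and 7.79% in PDGF-BB replicate 3, against 7.85% to 8.77% in the other 7, so an excess of a few genes is argued against in each. The test set before the result was seen asked for both shares inside the range of the others, which held for Control replicate 2 while PDGF-BB replicate 3 lay just below it. A difference between cultures or library preparations may remain, as the labels give no batch, and no biological explanation was tested.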
